A study of Homo sapiens with 4 samples.

How the data were processed

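RNA sequencing was compared across 4 libraries from 3 kinds of cultured human cells. Induced endothelial cells (iEC) were represented by 2 libraries, dermal microvascular endothelial cells from a commercial supplier (HMVEC) by 1 and the fibroblasts by 1. Per the labels' protocols, iEC were made by treating fibroblasts with the double-stranded RNA analogue poly I:C at 30 ng/ml for 7 days. The cells then received BMP-4 at 20 ng/ml, VEGF at 50 ng/ml and bFGF at 20 ng/ml for 7 days. Culture went on for 2 weeks with bFGF, VEGF and the cyclic AMP analogue 8-Br-cAMP at 0.1 mM. The iEC medium held 7.5% serum and 7.5% serum replacement at the start and 10% serum replacement at the end. Fibroblasts were grown with 10% serum, and HMVEC in an endothelial growth medium. Per the labels, total RNA was made into TruSeq libraries and read as single reads of 50 nt.

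Per the submitters' processing notes, TopHat and Cufflinks were used with the GRCh37/hg19 build, and their versions, settings and annotation were not given in the sources used here. The deposited signal is one expression value per gene. Each table had 66735 rows, of which 55040 held a value and 11695 did not (5555 rows with a symbol only and 6140 with an identifier). In every library exactly 11008 of the 55040 values were at least 1 and the lowest value was 0.01. The deposited values were therefore treated as length-normalized values of the FPKM type that had been scaled within each library to an 80th percentile of 1, with a floor of 0.01. That reading comes from the values and no label states the scaling. A gene at 0.01 is described as listed at 0.01, since the floor does not show absence.

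Depth was read from the low values. In genes with 1 annotated transcript, the low values followed steps whose size fell with transcript length, as whole reads give. Between 56.8% and 60.0% of low values lay within 0.1 of a whole number of reads, against 20.0% if evenly spread, so whole reads were not recovered and no count model was used. By these steps, a value of 1 on a transcript of 2000 nt stood for about 58.1 reads in iEC replicate 1, 52.0 in iEC replicate 2, 55.0 in HMVEC and 38.3 in the fibroblast library. A value of 0.0261 in the fibroblast library was worth 1 read at that length, so differences among values far below 1 were not detectable. Transcript lengths came from GENCODE release 29, whose build differs from that of the files, and no coordinates from it are given. The files hold no coordinates.

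Rows on chromosome Y and the genes of X inactivation, 515 in all, were left out of every step because the cultures came from people, which left 54525 genes. Genes with a value of at least 1 in at least 1 library were tested (13710). A gene that passes only through 1 group is highest there by construction, so its direction against the others is not a result. The tests were made with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean per group, a variance trend over expression, two-sided p-values and Benjamini-Hochberg adjustment over the genes tested. Log2 differences on this scale understate the change of low genes. The plan had assumed unscaled FPKM, and the same test was kept for the scaled values. A gene is called below at an adjusted p under 0.05. Only the 2 iEC libraries gave a residual degree of freedom (1), and limma added a prior of 0.9605. The lone HMVEC and fibroblast libraries were assumed to vary like the iEC libraries. HMVEC and fibroblast were compared by size alone, with a log2 difference of at least 2 (named 4-fold below). In every comparison, 4-fold apart means that difference on log2(value + 1), so genes at low values can miss it though their values lie further apart.

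The 2 iEC libraries were checked for being one library deposited more than once. Over 462 protein-coding genes with 1 transcript, the median chi-square of their reads was 0.679, against 0.455 from counting alone, and 14.7% of genes exceeded the 5% point. In the 120 of these genes with the most reads over the pair the median was 0.557. Summed over these genes the chi-square exceeded counting noise. Since whole reads were not recovered, error in the reads can add to this excess, and the check does not settle whether the libraries are separate cultures. Their values were not identical (COL1A2 was 6.11 and 0.31), and both were kept as replicates as labelled. Genes outside this set were not checked against counting noise, and over all 13710 genes tested the pair correlated less (0.915) than over protein-coding genes (0.986). The series text calls them 2 cultures without saying whether they were induced separately, so it is not known how much of the spread behind the p-values is technical.

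The fit was tested on simulated libraries for iEC against fibroblast, with 200 changed genes. These were drawn from genes with a mean iEC value of at least 2, and every gene was given a length of 2000 nt. The simulated iEC pair had counting noise only, less than the real pair showed. Recovery of low genes, or at the spread of the real pair, was therefore not simulated. With counting noise alone, where 11566 genes were tested, all 50 genes of each fold size (2, 4, 8 and 16) were recovered and 0.29% of unchanged genes were called. Where the lone libraries were given a coefficient of variation between cultures of 0.1, 0.2 or 0.3 (11624, 11678 and 11756 genes tested), the share of unchanged genes called was 21.1%, 44.9% and 58.9%. None of the unchanged genes was both called and 4-fold apart in these simulations (0 in each). No coefficient above 0.3 was simulated, so this does not vouch for the 4-fold counts in the data. Counts of genes called and at least 4-fold apart are given first for all genes and beside the counts of calls for the lists. Calls below that size can come from variation between cultures of the lone libraries, and calls above it are not shown to be free of it.

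Before the data were examined, 34 gene lists, a panel of 14 genes and the rule for named genes were fixed. The rule takes the 10 genes with the largest positive and the 10 with the largest negative difference among called genes (among 4-fold genes for HMVEC against fibroblast) with the same sign in both iEC libraries and a value of at least 10 in 1 library. It leaves out small RNA genes by prefix, HLA genes and clone names. It adds the panel and, per list, up to 4 members: the 2 with the largest difference and the 2 with the highest mean. NANOG and L1TD1 in the plot of genes by library, and genes described as chosen later, fall outside it. A list's median was also set against 10000 random lists matched on mean expression, as a description of these libraries. Gene names were those in the files, and 48616 of the identifiers matched the reference table of gene names. PECAM1, a panel gene, was not analysed here, and some genes that the rule takes are not reported here.

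The alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter on the mean, median-of-ratios scaling, quantile normalization, leaving out each iEC library, no variance trend and summing rows of a symbol. A further one, restricting to rows with an OK quantification status, was not run because the tables have no such column. Protein-coding genes only, and subtraction of a fibroblast share from iEC replicate 1, were added after the data were seen. The share was the median excess over fibroblast-specific genes at a minimum fibroblast value of 50, and minimums of 30 and 100 were also tried. Fibroblast-specific genes were protein-coding genes whose HMVEC value and mean iEC value each lay under 5% of the fibroblast value. HMVEC-specific genes were picked likewise, both from these same values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used besides R.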

Results

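Gene expression was measured by RNA sequencing in 2 libraries of induced endothelial cells (iEC, fibroblasts taken through poly I:C and endothelial growth factors), 1 library of dermal microvascular endothelial cells (HMVEC) and 1 of cultured fibroblasts. The title of the series asks how similar the 3 profiles are. Culture media, including serum and serum replacement, differed between the 3 kinds of cells, so effects of medium and of cell kind cannot be told apart. Effects of donor and passage were not separated either. Against fibroblasts, rose and fell mean higher and lower than in the 1 fibroblast library, which was not checked to be the parent culture of iEC. Values are the deposited expression values, scaled so that the 80th percentile of genes is 1 in every library, and differences are on log2(value + 1). In counts of genes, 4-fold and 2-fold mean differences of 2 and 1 on that scale, which low genes can miss with values further apart. In all counts below, a gene that reached 1 in only 1 group is highest there by construction. Means of iEC are given with the SD over the 2 libraries (n = 2), and HMVEC and fibroblast values come from 1 library each. By the steps of low values, a value of 1 on a transcript of 2000 nt stood for 58.1 and 52.0 reads in the iEC libraries, 55.0 in HMVEC and 38.3 in the fibroblast library.

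The iEC libraries stood closer to HMVEC than to fibroblast across genes, while HMVEC and fibroblast were about as close to each other as iEC was to HMVEC. Over the 13710 genes tested, Pearson's r with HMVEC was 0.753 for iEC replicate 1 and 0.748 for replicate 2. With the fibroblast library it was 0.695 and 0.687, and HMVEC against fibroblast gave 0.736. Spearman's rho gave the same order (0.691 and 0.690 with HMVEC, 0.626 and 0.621 with fibroblast, 0.679 for HMVEC against fibroblast). The iEC libraries correlated with each other at 0.915, and at 0.986 over the 11326 protein-coding genes. These are correlations across genes, which are not independent replicates, and no test was made of the differences between them.

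Compared with fibroblasts, iEC carried many endothelial transcripts. KDR (ENSG00000128052), the main VEGF receptor, stood at 26.1 ± 0.12 against 0.28 in the fibroblast library. TIE1, an endothelial receptor, stood at 32.5 ± 0.16 against 0.58, and TEK, the angiopoietin receptor, at 9.98 ± 0.06 against 0.30. NOS3, the endothelial nitric oxide synthase, was 13.8 ± 2.13 against 0.36. CDH5, the cadherin of endothelial junctions, rose less, to 4.38 ± 0.29 against 0.22 (log2 difference 2.13, SE 0.10, limma adjusted p = 0.0214). VWF, the clotting factor stored by endothelial cells, was 0.26 and 0.14 in the iEC libraries and 0.17 in fibroblasts, and was not called.

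Of the 29 measured pan-endothelial genes, 21 rose in iEC, 1 fell and 7 were not called, and adjusted over the list alone the counts were 21 and 1. The median log2 difference was 2.23, in the uppermost percentile of 10000 random lists matched on expression. EGFL7 rose (28.5 ± 1.15 against 3.96), while ENG was 16.6 ± 1.68 against 15.5 and was not called. Among 21 endothelial transcription factors, 10 rose and 4 fell (12 and 5 adjusted over the list alone). ERG reached 8.65 ± 0.55 against 0.13, FLI1 6.25 ± 0.02 against 0.98 and KLF4, also a reprogramming factor, 58.1 ± 0.72 against 2.34. ETV2, a factor of early vascular development, was under 1 in every library. Of 7 venous genes 5 rose and 1 fell (the same counts adjusted over the list alone), with APLNR, the apelin receptor, at 18.7 ± 0.13 against 0.12 and NRP2 at 35.6 ± 3.21 against 5.12. Of 16 arterial genes 6 rose and 4 fell (7 and 4 adjusted over the list alone). GJA5, a gap junction protein, rose to 12.9 ± 0.28 from 0.88, and NRP1 fell to 1.57 ± 0.08 from 24.8. Of 9 lymphatic genes 2 rose, TBX1 and FLT4 (1 adjusted over the list alone).

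**Figure D1:**
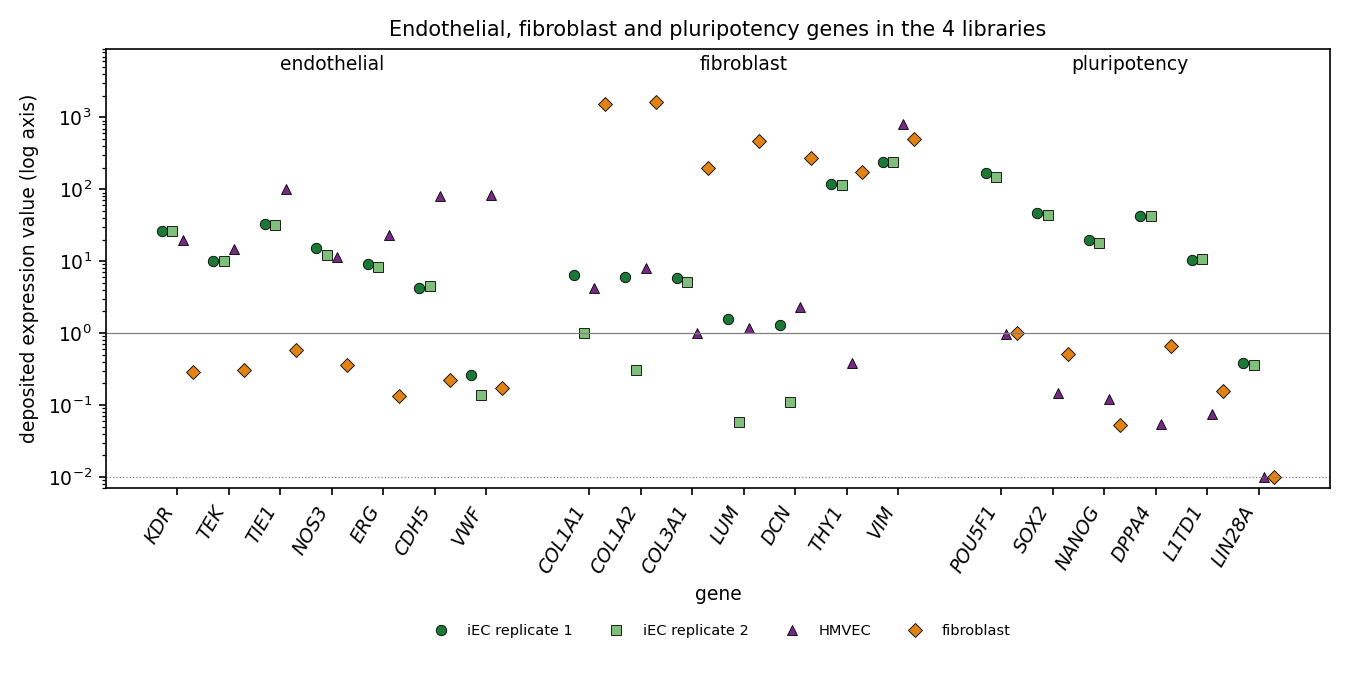
Deposited expression values (log axis; 1 is the 80th percentile of a library, the dotted line is the floor of 0.01) of endothelial, fibroblast and pluripotency genes, with 1 point per library. KDR was at 26.2 and 26.1 in the iEC libraries against 20.0 in HMVEC and 0.28 in fibroblasts, and POU5F1 at 166.9 and 150.5 against 0.96 and 1.01.

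Fibroblast genes fell almost throughout. Of 27 measured fibroblast genes, 23 fell, none (0) rose and 4 were not called, and 25 fell adjusted over the list alone (median log2 difference -3.63). LUM, a collagen-binding proteoglycan, was 0.81 ± 1.07 against 472 (log2 difference -8.16, SE 0.79, limma adjusted p = 0.0364). COL3A1, a fibrillar collagen, fell to 5.48 ± 0.61 from 196, MMP2 to 75.4 ± 1.70 from 430 and VIM, an intermediate filament, to 240 ± 0.27 from 500. THY1, a surface marker of fibroblasts, fell only to 115 ± 1.96 from 172, and was not called with quantile normalization. Of 33 fibroblast-specific genes, 30 were higher in iEC replicate 1 than in replicate 2. COL1A1 was 6.33 and 1.02 in the iEC libraries against 1556, and COL1A2 was 6.11 and 0.31 against 1611. Neither was called (limma adjusted p = 0.0501, SE 1.15 for COL1A1; 0.0647, SE 1.51 for COL1A2). Over the alternatives the limma adjusted p ranged from 0.0125 to 0.105 for COL1A1 and from 0.0176 to 0.130 for COL1A2. COL1A1 was called with the filter on the mean, with median-of-ratios scaling and with rows of a symbol summed. Both were called over protein-coding genes only and after 0.35% of the fibroblast value was subtracted from iEC replicate 1, which were alternatives chosen after the data were seen. The subtraction draws the 2 iEC libraries together for these genes by construction, so the calls after it are not further support.

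Matrix, contractile and growth factor genes fell with them. Of 30 genes of matrix remodelling 24 fell and 4 rose (25 and 4 adjusted over the list alone). FN1, fibronectin, fell to 6.32 ± 2.46 from 1066, THBS1 to 4.43 ± 2.74 from 1202 and SPARC to 266 ± 3.83 from 2551. Of 16 smooth muscle and pericyte genes 12 fell and 1 rose (12 and 2 adjusted over the list alone), with ACTA2, smooth muscle actin, at 3.26 ± 0.21 against 97.3 and TAGLN at 15.4 ± 3.31 against 498. Of 13 regulators of mesenchymal transition 5 fell and 1 rose (6 and 1 adjusted over the list alone), and CDH11 was 0.21 ± 0.15 against 78.0. Of 22 angiogenic growth factors 15 fell and 3 rose (16 and 5 adjusted over the list alone). FGF2 fell to 0.70 ± 0.10 from 31.6 and CTGF, a secreted matrix-associated protein, to 15.6 ± 1.06 from 240. WNT5A (0.26 ± 0.26 against 190), IGFBP3 (6.24 ± 2.70 against 1293), DCN (0.71 ± 0.85 against 273), COL6A3 (0.36 ± 0.44 against 180), GREM1, LOX and ALDH1A1 were among the 10 largest decreases of called genes that the naming rule takes, which leaves out most small RNA genes.

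Genes of pluripotency and of cell division rose. POU5F1 (ENSG00000204531), the transcription factor OCT4, was 159 ± 11.6 against 1.01 in fibroblasts (log2 difference 6.31, SE 0.11, limma adjusted p = 0.0187) and 0.96 in HMVEC. SOX2 was 44.9 ± 1.66 against 0.50. All 7 measured genes of the 14 in the pluripotency list rose, also adjusted over the list alone (7), with a median log2 difference of 4.25. Apart from POU5F1 these passed the filter only through iEC, so it fixed their direction. The other 7 were under 1 in every library, among them LIN28A at 0.38 and 0.36. POU5F1P3, a processed copy of POU5F1 that can share its reads, was 47.3 ± 1.55 against 0.43, so part of either value is uncertain. Values per gene also do not separate transcripts of a cell's own gene from those of an introduced copy, although the protocol given above names no introduced gene. All 22 proliferation genes rose, also adjusted over the list alone (22; median 2.40), with CCNB1, a mitotic cyclin, at 38.0 ± 1.94 against 2.96 and PCNA at 38.5 ± 0.43 against 9.61. Of 16 genes of arrest and senescence 10 fell and 2 rose (10 and 3 adjusted over the list alone). IGFBP7 fell to 27.8 ± 0.39 from 258. The largest increases of called genes that the rule takes were SPP1, the secreted phosphoprotein osteopontin (658 ± 4.38 against 2.69), POU5F1, the imprinted RNA H19 (554 ± 22.0 against 6.42) and FAM9C (84.1 ± 4.99 against 0.24). LPL, lipoprotein lipase (69.5 ± 1.92 against 0.76), ALDH1A2 (98.1 ± 2.36 against 2.47), CALB1 (36.0 ± 1.55 against 0.31) and SOX2 followed. VTRNA1-3, a short RNA gene, was 58.3 and 32.5 in iEC and listed at 0.01 in the other libraries.

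Innate immune genes are of interest because poly I:C is a ligand of TLR3. In the protocol it was given for 7 days, before 7 days of growth factors and 2 weeks of further culture. The values below are therefore no measure of the early response to poly I:C. Of 33 interferon-stimulated genes 24 fell, none (0) rose and 9 were not called, and 26 fell adjusted over the list alone (median -2.03). IFI6 fell to 3.17 ± 0.60 from 119, XAF1 to 0.02 ± 0.01 from 16.8 and IFITM1 to 12.1 ± 0.48 from 72.5. TLR3 itself was listed at 0.01 in both iEC libraries and under 1 in the others. Of 14 genes of the TLR3 and NF-kB pathway 1 fell, RELA (8.46 in both libraries against 11.9, not called with quantile normalization), and 0 did adjusted over the list alone. Of 16 cytokines and adhesion molecules 8 fell and 8 were not called (8 adjusted over the list alone). CCL2, a monocyte chemokine, fell to 0.61 ± 0.05 from 26.6, and PTGS2 to 0.09 ± 0.01 from 18.9. Of 36 chromatin modifiers 12 rose and 1 fell (the same adjusted over the list alone), with DNMT1 at 9.99 ± 0.06 against 1.78 and HDAC2 at 56.1 ± 3.40 against 22.0. NOS2, a panel gene, was under 1 in every library.

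Metabolic and signalling lists moved in both directions. Of 22 cholesterol synthesis genes 18 rose (19 adjusted over the list alone), led by SQLE at 96.7 ± 2.16 against 3.29, with FDPS at 62.2 ± 2.29 against 13.4. Of 17 glycolysis and hypoxia genes 8 fell and 1 rose (11 and 2 adjusted over the list alone), and ADM was 1.49 ± 0.23 against 89.3. Of 15 genes of unfolded protein and amino acid stress 9 fell and 2 rose (the same adjusted over the list alone), with CHAC1 at 0.41 ± 0.01 against 17.6. Of 13 mitochondrially encoded genes 7 rose (11 adjusted over the list alone), with MT-ND2 at 554 ± 0.31 against 269. Of 17 FGF and MAPK-responsive genes 7 rose and 2 fell (8 and 2 adjusted over the list alone), with DUSP6 at 44.9 ± 2.52 against 8.21. Of 13 cAMP-responsive genes 3 rose and 4 fell (the same adjusted over the list alone), with RGS2 at 55.0 ± 0.71 against 4.74. Of 13 BMP-responsive genes 3 rose and 5 fell (3 and 6 adjusted over the list alone), with ID2 at 7.55 ± 1.08 against 80.4. Of 6 histone genes 4 fell (5 adjusted over the list alone). Of 13 housekeeping genes 4 fell and 2 rose (4 and 6 adjusted over the list alone), with GAPDH at 364 ± 13.6 against 914.

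Markers of other cell types were mixed, or for leukocyte, erythroid and melanocyte genes mostly under 1 in every library. SPP1 of the osteo-chondrogenic list and LPL of the adipocyte list were among the largest increases given above. Of 6 measured epithelial genes 2 rose and 2 fell (2 and 3 adjusted over the list alone). KRT8 was 95.6 ± 0.76 against 9.78 and KRT18 76.3 ± 1.77 against 38.6, while KRT19 fell to 0.14 ± 0.09 from 14.9. Of 5 neural genes 2 rose (3 adjusted over the list alone), NES at 39.8 ± 0.51 against 7.79 and NCAM1 at 9.88 ± 1.31 against 0.30. Of 8 adipocyte genes 4 rose and 1 fell, of 6 osteo-chondrogenic genes 2 rose and 3 fell, and of 7 mesoderm and vascular progenitor genes 3 rose and 3 fell (4 and 1, 2 and 3, 4 and 3 adjusted over the list alone). The only measured leukocyte gene was CD68 (0.30 ± 0.16 against 8.11) and the only measured melanocyte gene MITF (0.07 ± 0.01 against 2.75), both lower, also adjusted over the list alone (1 each). No erythroid gene reached 1 in any library (0 measured).

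Called and at least 4-fold apart from fibroblasts were fewer members of most lists. The size is a difference of at least 2 on log2(value + 1). DNMT1, FLI1 and FLT4 missed it although their values lay more than 4-fold apart. The counts of higher and lower members were 16 and 1 for pan-endothelial genes, 2 and 1 for endothelial transcription factors, 2 and 1 for arterial, 3 and 1 for venous and 0 and 0 for lymphatic genes. They were 0 and 19 for fibroblast, 2 and 14 for matrix, 1 and 7 for smooth muscle, 0 and 5 for mesenchymal transition and 0 and 7 for angiogenic growth factor genes. Pluripotency genes had 5 and 0, proliferation 19 and 0, arrest and senescence 1 and 4, interferon-stimulated genes 0 and 17, TLR3 and NF-kB 0 and 0, cytokines and adhesion molecules 0 and 3, and chromatin modifiers 0 and 0. Cholesterol synthesis had 5 and 0, glycolysis and hypoxia 0 and 3, stress 0 and 5, mitochondrial genes 0 and 0, FGF and MAPK 5 and 0, cAMP 2 and 1, BMP 2 and 2, histones 0 and 1 and housekeeping genes 0 and 1. Epithelial genes had 1 and 2, neural 2 and 0, adipocyte 3 and 0, osteo-chondrogenic 1 and 2 and mesoderm and vascular progenitor genes 1 and 2, with CD68 past this size and MITF not.

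In all, 452 genes were called higher and at least 4-fold apart in iEC than in fibroblasts, and 676 were lower. Without the size condition, 2452 were called higher and 2529 lower by limma, all 4981 with the same sign in both iEC libraries. The shared sign follows from the fit, which takes its spread from the iEC pair, and is no further check. The number called and 4-fold apart was 1072 higher and 1124 lower with a pseudocount of 0.1, where LUM, DCN, COL6A3, LOX and CD68 were not called, and 1485 genes were called higher and 3123 lower without the filter, where these, THBS1, IGFBP3, FN1, FLT4, RELA, HDAC2 and VTRNA1-3 were not. Since the lone fibroblast library was given the spread of the iEC libraries, differences well below 4-fold are not separated from variation between fibroblast cultures.

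**Figure D2:**
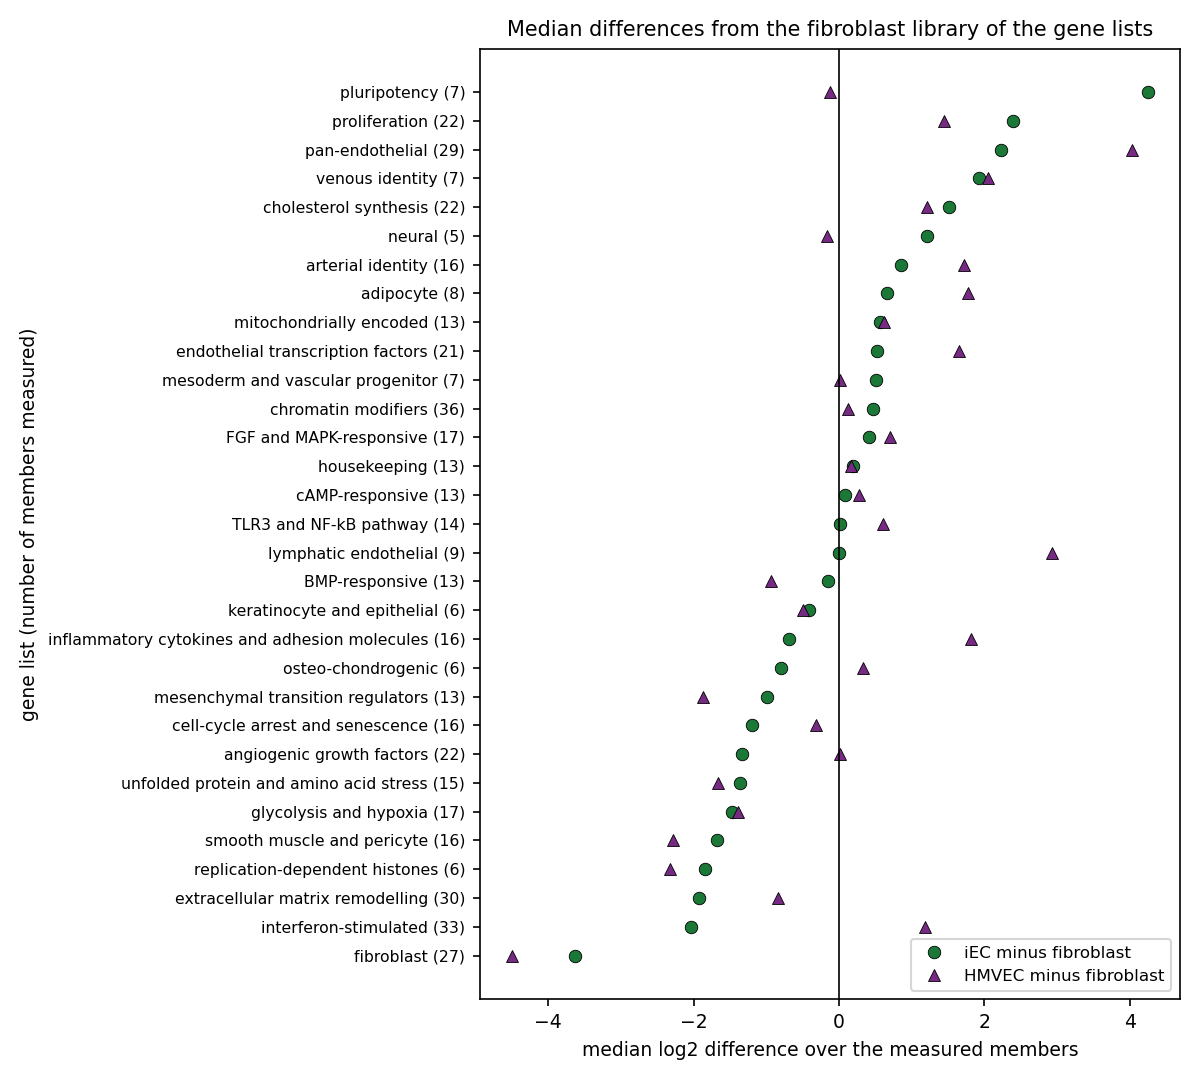
Median log2 difference from the fibroblast library over the measured members of 31 gene lists (those with at least 3), for the mean of the 2 iEC libraries (circles) and for HMVEC (triangles). Pan-endothelial genes have a median of 2.23 in iEC and 4.03 in HMVEC, fibroblast genes -3.63 and -4.50, and interferon-stimulated genes -2.03 and 1.18.

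Against HMVEC, most endothelial genes on the fixed lists were lower in iEC. KDR (26.1 ± 0.12 against 20.0, log2 difference 0.37), TEK (9.98 ± 0.06 against 14.9, log2 difference -0.53) and NOS3 (13.8 ± 2.13 against 11.4, log2 difference 0.25) were not called, which does not show equal levels. VWF was 0.20 ± 0.09 in iEC against 82.9 in HMVEC (log2 difference -6.13, SE 0.12, limma adjusted p = 0.0222), and CDH5 was 4.38 ± 0.29 against 79.9. Of 29 pan-endothelial genes 19 were lower in iEC and 10 not called, with a median log2 difference of -1.85 (24 lower and 1 higher adjusted over the list alone). VWF, MMRN1, CLEC14A, ESM1 and STAB1 passed the filter only through HMVEC, so it fixed their direction. MMRN1, a platelet and endothelial protein, was 0.19 ± 0.12 against 122, EGFL7 28.5 ± 1.15 against 152 and ENG 16.6 ± 1.68 against 115. Of 21 endothelial transcription factors 15 were lower and 1, KLF4, higher (16 and 1 adjusted over the list alone). The same limit holds for TAL1, SOX17, MECOM, FOXC2 and BCL6B. ERG was 8.65 ± 0.55 against 23.3 and FLI1 6.25 ± 0.02 against 17.2. All 9 lymphatic genes were lower, also adjusted over the list alone (9), with PDPN at 0.09 ± 0.01 against 52.9. Apart from FLT4 and TBX1 they passed the filter only through HMVEC, so it fixed their direction. Of 16 arterial genes 10 were lower and 3 higher (12 and 3 adjusted over the list alone), with ACVRL1 at 6.07 ± 0.24 against 38.8. DLL4, CXCR4, BMX and DEPP1 also passed only through HMVEC. Of 7 venous genes 2 were lower and 2 higher (4 and 2 adjusted over the list alone), with NR2F2, a venous transcription factor, at 1.69 ± 0.44 against 24.5 and APLNR at 18.7 ± 0.13 against 0.05.

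The pluripotency genes stood as far above HMVEC as above fibroblasts, with all 7 measured genes higher (median 4.16; 7 adjusted over the list alone). Here too all but POU5F1 passed the filter only through iEC. Fibroblast genes were mixed against HMVEC, with 9 of 27 higher and 3 lower (9 and 4 adjusted over the list alone). THY1 was 115 ± 1.96 against 0.38, COL6A1 53.1 ± 2.24 against 1.85 and MMP2 75.4 ± 1.70 against 4.48. COL3A1 was also higher (5.48 ± 0.61 against 1.00). COL1A1 (log2 difference -0.45, SE 1.15, limma adjusted p = 0.793) was not called. Its difference was -1.38 without iEC replicate 1 and 0.48 without replicate 2. With the fibroblast share subtracted from iEC replicate 1 it was -1.43 (limma adjusted p = 0.0343). That call does not show a lower level. The share came from the excess of replicate 1 over replicate 2 in genes that include COL1A1, and nothing was subtracted from HMVEC. SPP1, H19, POU5F1, FAM9C, CKB, LPL and ALDH1A2 were among the 10 largest positive differences of called genes that the rule takes, with CKB, a creatine kinase, at 102 ± 3.15 against 0.75. The largest negative ones held EFEMP1 (1.32 ± 0.71 against 920), KRT7 (0.39 ± 0.25 against 259), FN1 (6.32 ± 2.46 against 762.3), THBS1, S100A6, MGP and ABI3BP. The short RNA gene snoU2-30 was listed at 0.01 in iEC and at 100 in HMVEC.

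Immune and secreted factors were the other large group below HMVEC. Of 33 interferon-stimulated genes 30 were lower and 1, IFITM1, higher (31 and 1 adjusted over the list alone; median -2.84), with MX1 at 0.11 ± 0.03 against 57.7 and ISG15 at 1.91 ± 0.22 against 97.4. ISG20, OASL, RSAD2, CXCL10 and CXCL11 passed the filter only through HMVEC, so it fixed their direction. After subtraction of the fibroblast share, the log2 difference of IFITM1 went from 0.77 to 0.76 and its limma adjusted p from 0.0454 to 0.0535 (0.0192 to 0.0692 over the alternatives), so the call ended with almost no change in size. Of 16 cytokines and adhesion molecules 15 were lower (15 lower and 1 higher adjusted over the list alone), with CCL2 at 0.61 ± 0.05 against 118 and IL8, a neutrophil chemokine, at 1.68 ± 0.30 against 146. The direction of CCL5, CCL20, CXCL2, CXCL3, CXCL5, SELE and CSF3 was fixed by the filter, which they passed only through HMVEC. Of 22 angiogenic growth factors 11 were lower and 1 higher (13 and 2 adjusted over the list alone), with EDN1, endothelin, at 1.52 ± 0.08 against 84.1. Of 30 matrix genes 19 were lower and 3 higher (20 and 4 adjusted over the list alone). Of 16 arrest and senescence genes 6 were lower and 2 higher (11 and 2 adjusted over the list alone). Of 22 proliferation genes 11 were higher (20 adjusted over the list alone), with PCNA at 38.5 ± 0.43 against 17.0. Of 22 cholesterol genes 5 were higher and 1 lower (the same adjusted over the list alone), and SQLE was 96.7 ± 2.16 against 11.2.

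In the other lists against HMVEC, the counts of higher and lower members were as follows. They were 4 and 2 of 16 for smooth muscle and pericyte, 1 and 3 of 13 for mesenchymal transition, 0 and 2 of 14 for TLR3 and NF-kB, 3 and 0 of 36 for chromatin modifiers, and 1 and 2 of 7 for mesoderm and vascular progenitor. They were 2 and 3 of 13 for cAMP, 4 and 0 of 13 for BMP, 5 and 2 of 17 for FGF and MAPK, 1 and 4 of 8 for adipocyte, and 1 and 2 of 6 for osteo-chondrogenic. Glycolysis and hypoxia had 2 and 1 of 17, stress 4 and 1 of 15, epithelial 2 and 2 of 6, neural 2 and 0 of 5, mitochondrial 2 and 2 of 13, histones 0 and 0 of 6, and housekeeping 0 and 2 of 13. CD68 was lower and MITF was not called. Adjusted over the list alone, in the same order, the counts were 6 and 4, 1 and 3, 0 and 1, 0 and 0, 3 and 3 for the first 5 lists, and 2 and 4, 5 and 0, 8 and 4, 3 and 5, 1 and 2 for the next. For the rest they were 2 and 1, 4 and 1, 2 and 2, 3 and 0, 4 and 3, 0 and 0, and 1 and 3, while CD68 and MITF were both lower (1 each).

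Of the lists against HMVEC, the members called and at least 4-fold higher or lower were 0 and 14 for pan-endothelial genes, 1 and 9 for endothelial transcription factors, 1 and 5 for arterial, 1 and 2 for venous and 0 and 8 for lymphatic genes. They were 6 and 0 for pluripotency, 6 and 0 for fibroblast, 0 and 25 for interferon-stimulated, 0 and 11 for cytokine and adhesion, 0 and 7 for angiogenic growth factor, 2 and 11 for matrix, 0 and 3 for arrest and senescence, 0 and 0 for proliferation and 2 and 0 for cholesterol synthesis genes. In each of the remaining lists there were at most 2 higher and 2 lower.

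By limma, 251 genes were called and at least 4-fold higher in iEC than in HMVEC and 587 lower, out of 1274 called higher and 1782 called lower. In both comparisons at once, 159 genes were called and at least 4-fold higher in iEC and 156 lower. With a pseudocount of 0.1, 630 genes were called and 4-fold higher, and THBS1, S100A6 and CD68 were not called. Without the filter 576 genes were called higher and 2223 lower, and those 3 genes, EFEMP1, FN1, ERG, COL3A1, ENG, NR2F2 and IFITM1 were not called, while 1992 were called higher and 2316 lower over protein-coding genes only.

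HMVEC and fibroblast, compared without replicates, differed by 4-fold or more in 585 genes higher in HMVEC and 565 higher in fibroblasts, so these counts have no replicate check and no p-value. Higher in HMVEC were TIE1 (99.3 against 0.58), VWF (82.9 against 0.17), CDH5 (79.9 against 0.22), MMRN1 (122 against 0.37), ANKRD1 (147 against 0.69), FABP4, a fatty acid carrier (83.8 against 0.15), HHIP (84.6 against 0.17) and TM4SF1 (124 against 1.16). ECSCR was 274 in HMVEC and listed at 0.01 in fibroblasts. Higher in fibroblasts were COL1A1 (1556 against 4.26), COL1A2 (1611 against 7.94), IGFBP3 (1293 against 2.36), LUM, WNT5A, THY1, COL6A3, SULF1, FBLN1 and PSG5. At least 4-fold higher in HMVEC were 28 of 29 pan-endothelial genes and 8 of 9 lymphatic genes, and at least 4-fold lower were 23 of 27 fibroblast genes. With a pseudocount of 0.1 the counts were 1186 and 1203, and over protein-coding genes 387 and 411.

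Genes at least 4-fold apart between HMVEC and fibroblast were followed in iEC. Of the 565 fibroblast-high genes, 453 (80.2%) fell in iEC, 379 of them at least 4-fold, and 5 rose. The median gene lay at 0.972 of the way from the fibroblast to the HMVEC value (interquartile range 0.607 to 1.013), where 0 is fibroblast and 1 is HMVEC. Of the 585 HMVEC-high genes, 192 (32.8%) rose in iEC, 101 of them at least 4-fold, 36 fell and 357 were not called, and the median gene lay at 0.202. It lay at 0.119 in iEC replicate 1 alone and at 0.128 in replicate 2 alone. With a pseudocount of 0.1 the shares were 57.4% of the fibroblast-high genes (median position 0.854) and 37.9% of the HMVEC-high genes (0.419), and without the filter the shares were 67.1% and 21.9%. Over protein-coding genes, 197 of 387 HMVEC-high genes rose (50.9%), with a median position of 0.242 (interquartile range -0.014 to 0.609; 0.230 and 0.243 in the single libraries). On that set, 376 of 411 fibroblast-high genes fell (91.5%), with a median position of 0.955 (interquartile range 0.645 to 1.04). Between iEC and HMVEC, 194 of these 411 genes (47.2%) and 335 of the 387 HMVEC-high genes (86.6%) were called. Of the 585 HMVEC-high genes, 128 were within 2-fold of HMVEC in iEC. A culture low in the specific genes of both cell types would by construction also lie near 1 for the fibroblast-high genes and near 0 for the HMVEC-high genes, so the difference between the sets does not by itself measure a likeness to HMVEC.

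Both sets of differences use the same fibroblast library, so part or all of the shared movement could arise from it. Independent lists of these sizes would share 104.6 genes for the HMVEC-high set and 104.2 for the fibroblast-high set. The differences of iEC and of HMVEC from fibroblast correlated at 0.589 across genes, against 0.578 in simulated unchanged groups. The simulated correlation follows from the shared library at any spread that all libraries have in common, and the observed one was close to it. Their covariance was 0.984, against 0.129 simulated. The simulation gave every library the spread of the iEC pair and so left out variation between fibroblast cultures, which makes the simulated covariance small. The fibroblast library could not be split, so part or all of the excess may come from it.

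**Figure D3:**
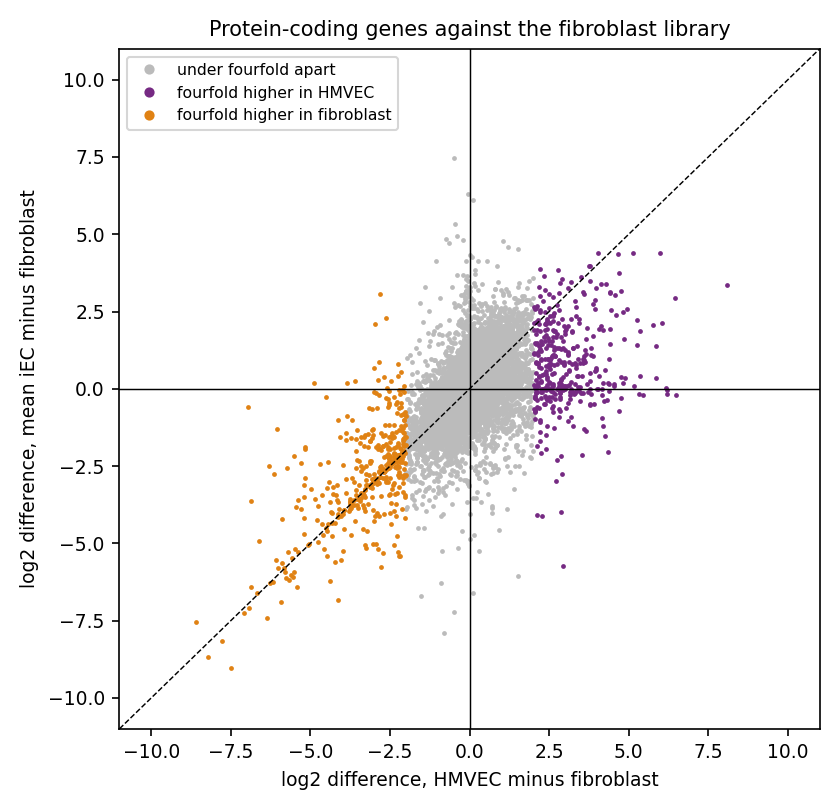
Log2 difference from the fibroblast library of HMVEC (x axis) and of the mean of the 2 iEC libraries (y axis) for 11326 protein-coding genes, with 387 genes 4-fold higher in HMVEC in purple, 411 4-fold higher in fibroblasts in orange and the line of equal difference dashed. The median position is 0.955 for the orange genes (interquartile range 0.645 to 1.04) and 0.242 for the purple genes (-0.014 to 0.609), where 1 is the dashed line.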

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

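Of the alternatives below, protein-coding genes only and subtraction of the fibroblast share were chosen after the data were seen, and the others were planned. The cause was not tested where none is given. No called gene taken by the rule for named genes changed sign under these alternatives. Of the 4981 genes called in iEC against fibroblast, 97.4% were kept with median-of-ratios scaling, 95.2% with quantile normalization (3 had the opposite sign), 95.9% without the variance trend and 98.9% with the share subtracted. Of the 3056 called against HMVEC these kept 99.5%, 89.7% (1 had the opposite sign), 89.2% and 97.5%. Those scalings left the median log2 difference of all genes between -0.001 and 0.074. With a pseudocount of 0.1, 89.3% and 79.5% were kept, and without the filter, where 27136 genes were tested, 56.3% and 45.9%. The share of calls that were higher was 32.2% and 20.6% without the filter, against 49.2% and 41.7%. No paired analysis was possible because the HMVEC and fibroblast groups hold 1 library each. Rows with an OK status were not run, since the tables have no such column. Leaving out an iEC library leaves no residual degree of freedom, so those are values with no test. Depth limits low genes most in the fibroblast library, where 1 read on 2000 nt is worth 0.0261.

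A pseudocount of 0.1 stretches low values by construction. It gave 1072 genes called and 4-fold higher and 1124 lower in iEC against fibroblast, and 630 higher against HMVEC. By size alone, 1520 were 4-fold higher and 1518 lower against fibroblast, 1090 and 1265 against HMVEC, and 1186 and 1203 in HMVEC against fibroblast. The correlation of iEC (mean of 2 libraries) was 0.599 with fibroblast and 0.662 with HMVEC, that of HMVEC with fibroblast 0.646 and that of the iEC libraries 0.872. The median position was 0.419 for HMVEC-high genes and 0.854 for fibroblast-high genes.

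Without the filter, more genes enter the adjustment and the correlations. The genes called higher in iEC were 1485 against fibroblast and 576 against HMVEC, while those called lower were 3123 and 2223 (2529 and 1782 with the filter), and 48 members of the fixed gene lists were called higher against HMVEC (79 with the filter). The correlations in the same order were 0.828, 0.862, 0.853 and 0.952. With a mean value of at least 1 they were 0.653, 0.715, 0.707 and 0.903, and with rows of a symbol summed 0.701, 0.762, 0.745 and 0.928. The median position of HMVEC-high genes was 0.231 with the mean filter, 0.242 with rows summed, 0.187 with median-of-ratios scaling and 0.189 with quantile normalization. Over protein-coding genes only, 1992 genes were called higher against HMVEC. At least 4-fold higher were 383 against fibroblast, 207 against HMVEC and 387 in HMVEC against fibroblast. There the correlations were 0.729, 0.797, 0.773 and 0.986, 50.9% of HMVEC-high genes were called towards HMVEC, and the median positions were 0.242 and 0.955.

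Without iEC replicate 1 or 2, the median position was 0.119 to 0.128 for HMVEC-high genes and 0.977 to 0.999 for fibroblast-high genes. Of 66 list medians, 51 moved by more than the spread between the iEC libraries with a pseudocount of 0.1, 30 without the filter and 21 (of 64) with the mean filter. There were 23 that moved with quantile normalization, 19 with median-of-ratios scaling, 18 without iEC replicate 1 and 20 without iEC replicate 2. Of 132 counts of list members called, 44 moved by over 1.5 times without the filter. Medians near 0 and that of the mesoderm list also changed sign, and the cause was not tested. In iEC against fibroblast, that of the TLR3 and NF-kB pathway (0.01) was -0.04 with median-of-ratios scaling and -0.10 to -0.05 with a library left out. That of cAMP-responsive genes (0.08) was -0.13 without the filter and -0.49 with the mean filter, and that of mesoderm and vascular progenitor genes (0.51) was -1.63 with the mean filter. Against HMVEC, the medians were 0.15 for mesoderm and vascular progenitor genes without the filter (-0.21 with it), 0.15 for keratinocyte and epithelial genes with the mean filter (-0.01) and 0.03 for mitochondrially encoded genes with quantile normalization (-0.01).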

Other observations

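The groupings and checks in this part were chosen only after the values were seen, as were its genes outside the fixed lists and the naming rule. H19 is taken by that rule, and KLF4 and the members of the pluripotency list are in the fixed lists. HOX genes, transcription factors of position along the body axis, are given here by paralog group, with a division chosen from these same values and so not tested. Of 17 tested genes of groups 1 to 8, 14 rose in iEC and 0 fell (limma, Benjamini-Hochberg adjustment), with a median log2 difference of 1.78. HOXD1 was 7.47 and 7.02 in the iEC libraries against 0.077 in fibroblasts and 3.28 in HMVEC. Of 8 tested genes of groups 9 to 13, 4 fell (HOXA10, HOXA11, HOXA13 and HOXC10) and 1 rose (HOXD9), with a median of -1.61. HOXA10 was 0.98 and 0.91 in iEC against 12.5 in fibroblasts and 2.56 in HMVEC. HOXA13 was 0.046 and 0.01 in iEC against 4.23, and listed at 0.01 in HMVEC.

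Values of 6 imprinted genes are given without a test of imprinted genes as a group. MEG3, a maternally expressed long RNA, was 0.24 and 0.029 in the iEC libraries against 43.9 in fibroblasts and 48.6 in HMVEC, while H19 was 570 and 539 against 6.42 and 1.56. IGF2, a neighbour of H19, was 3.77 and 4.13 against 13.9 and 0.13. MEST was 1.45 and 1.59 against 29.7 and 0.71, NDN 0.13 and 0.20 against 7.54 and 0.098, and SNRPN 7.30 and 5.30 against 0.50 and 0.24. Among genes known from pluripotent cells, GDF3 was 11.3 and 10.3 against 0.045 in fibroblasts and listed at 0.01 in HMVEC, and ESRG was 33.1 and 32.5 against 0.25 and 0.11.

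Pluripotency genes stood high in both iEC libraries. The protocol given above names no introduced factor or vector. Outside the factors POU5F1, SOX2, NANOG, LIN28A and LIN28B, 4 list members were called higher (DPPA4, TDGF1, UTF1 and L1TD1). They passed the filter only through iEC, so it fixed their direction. Any reads of vectors for those named factors would not account for their levels. DPPA4 was 42.4 in both iEC libraries, while UTF1 was only 1.63 and 1.55. For the factors POU5F1, SOX2, KLF4 and MYC, all 4 of which rose, any vector reads and the cells' own transcripts cannot be told apart, since only values per gene are given. Undifferentiated pluripotent cells in the cultures also stay open, as no pluripotent library is at hand. The median of 6 other transcripts of such cells (LIN28A, EPCAM, CDH1, ZFP42, SALL4 and DNMT3B) was only 0.13% of POU5F1, whose own level could hold vector reads if there were any, while NANOG, DPPA4, L1TD1, GDF3 and ESRG were high. Expression brought about by the induction protocol stays open as an untested explanation.

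Fibroblast transcripts were higher in iEC replicate 1 than in replicate 2, in 30 of 33 fibroblast-specific genes, by a median of 0.35% of their fibroblast level (exact binomial p = 1.4e-06, two-sided, over genes that are not independent). For HMVEC-specific genes it was 11 of 17 (exact binomial p = 0.332). Those 17 genes stood at a median of 0.901% and 1.023% of their HMVEC level in the iEC libraries and 0.763% in the fibroblast library. A scaling or depth difference is argued against by the median log2 difference between the iEC libraries, which was 0.42 higher in those 33 genes than over 11326 protein-coding genes. Fibroblasts left in the culture of replicate 1 cannot be told apart from reads crossing between libraries, because the HMVEC library also held a median of 0.518% of the fibroblast level, against 0.691% and 0.303% in the iEC libraries.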
